A study of Macaca mulatta with 8 samples.

How the data were processed

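The series holds 8 libraries of total RNA from the striatum of rhesus macaques (Macaca mulatta), typed by the submitters as non-coding RNA profiling. Per the labels' protocols, brains were frozen, RNA was extracted with a Norgen kit, and 500 ng of total RNA entered an Illumina TruSeq RNA library. The only table used here is a read summary deposited by the authors, and its values are raw counts of reads per library at 5 processing steps, with no normalization and no gene or microRNA. Per the file's row labels, the authors counted the raw reads, the reads containing "3ADT" (read here as the 3′ sequencing adapter), the reads under 15 (read here as inserts shorter than 15 nucleotides), the reads left after the adapter step, and the mappable reads. The last of these steps has no definition in the labels or the file. The adapter trimmer, the aligner, the genome build and the miRNA reference are not given in the sources used here. Values per microRNA were not analysed here.

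The table was checked for internal arithmetic. In all 8 libraries the adapter-containing count minus the count under 15 equalled the count after the adapter step exactly, so the reads under 15 and the reads left after the adapter step divide the adapter-containing reads between them. This check does not bear on the mappable reads. The deposited column of sums equalled the sum of the 8 libraries in all 5 rows. Columns were matched to samples by the sample description, and 0 columns were left unmatched.

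The 4 measures of composition computed from the deposited counts were adapter-containing reads as a percent of raw reads, short-insert reads as a percent of adapter-containing reads, mappable reads as a percent of trimmed reads (those left after adapter removal and the length limit), and mappable reads as a percent of raw reads. Library totals were compared as log2 raw reads. These choices follow from the order of the steps. If an earlier step loses more reads in some libraries, percentages of raw reads at all later steps move with it, and percentages of the reads entering a step do not. A count model across genes was not used, because the table has no genes, although the design fixed beforehand had a count model ready for a table of microRNAs.

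The samples form a 2 by 2 layout of infection with simian immunodeficiency virus (SIV) and treatment with Δ9-tetrahydrocannabinol (THC), with 2 libraries per group. Infection and THC were each tested as 4 libraries against 4, by an exact two-sided permutation test of the difference of means over all 70 arrangements. The smallest p that this test can give is 0.0286. The interaction was tested as the difference of the infection differences under THC and under vehicle, over the reassignments of all 8 libraries to the groups. Contrasts of 2 libraries against 2 have 6 arrangements, and their exact permutation test cannot go below p = 0.333. Benjamini-Hochberg adjustment covered the 12 tests of shares (4 measures by infection, THC and interaction), and separately the 3 tests of library totals. For the comparisons of 4 against 4, an interval at 97.1% confidence was obtained by inverting the permutation test. The sample descriptions give each library its own identifier. The labels do not say whether replicates are separate animals. The p-values treat the libraries as exchangeable units, and they bear on animals only if each library came from a separate one.

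Depth ranged from 16.9 to 24.3 M raw reads (M, mega-reads). At that depth the widest 95% Wilson interval of any share in any library was 0.0288 percentage points. Wilson intervals cover counting error only, since reads amplified by PCR are not independent molecules. Replicates of a group differed by at least 0.770 percentage points in the short-insert share, more than counting error, so no pair was treated as a repeat deposit of the same reads. This does not show that replicates came from separate animals or preparations.

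The comparison of the short-insert share was tested on simulated data with 400 draws per setting, at the real depths and with an SD of 1.2 percentage points between libraries. That SD was the mean of the SDs within the 4 groups of these same data, each from 2 libraries. Values were drawn as normal with it in every group, while the observed group SDs ran from 0.545 to 1.83. The unadjusted test at 0.05 called 4% of draws with no difference, 39% with a difference of 2 percentage points, and 92.5% with a difference of 4 percentage points. With no difference and a common SD, the 70 arrangements set the rate of calls close to 0.0286 beforehand. The 4% therefore does not show how the test behaves with unequal spreads or a batch.

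Alternatives were permutation within levels of the other factor, permutation within the replicate numbers of the titles, an untransformed or logit scale, a difference of medians, another denominator, and leaving out each library in turn. These and the groups, tests and reporting rule (every library and every category of reads, with no gene named) were chosen before the data were examined. Added after seeing the data were 2 further units for the short-insert reads, and the split of libraries into sets by the share of reads without adapter (under 1%, 1% to 3%, over 3%). The computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.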

Results

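Reads from 8 libraries of macaque striatum were followed through adapter removal and mapping. The striatum is a basal ganglia structure of the forebrain. SIV is a lentivirus of non-human primates that is used to model HIV infection, and THC is the main psychoactive compound of cannabis. The groups were vehicle, THC, SIV with vehicle, and SIV with THC, each with 2 libraries. The series asked how THC affects the microRNA profile of the infected striatum. The values analysed here describe the make-up of the libraries from which such a profile is counted.

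The libraries held 168 M raw reads together, of which 155 M were mappable. Raw reads per library were 21.9 M ± 3.29 (SD, n = 2) for vehicle and 22.0 M ± 0.83 (SD, n = 2) for THC. They were 20.9 M ± 0.450 (SD, n = 2) for SIV with vehicle and 19.4 M ± 3.54 (SD, n = 2) for SIV with THC. The smallest library was SIV with THC replicate 2, at 16.9 M, and the largest was vehicle replicate 1, at 24.3 M. Infected libraries held 0.913 times the reads of uninfected ones, as a ratio of geometric means over 4 libraries each (exact permutation p = 0.314, adjusted p = 0.714). The corresponding ratio for THC over vehicle was 0.964 (exact permutation p = 0.714, adjusted p = 0.714). The interaction in log2 reads was -0.13 (exact permutation p = 0.629, adjusted p = 0.714). Differences in depth between groups were within the spread between libraries.

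**Figure D1:**
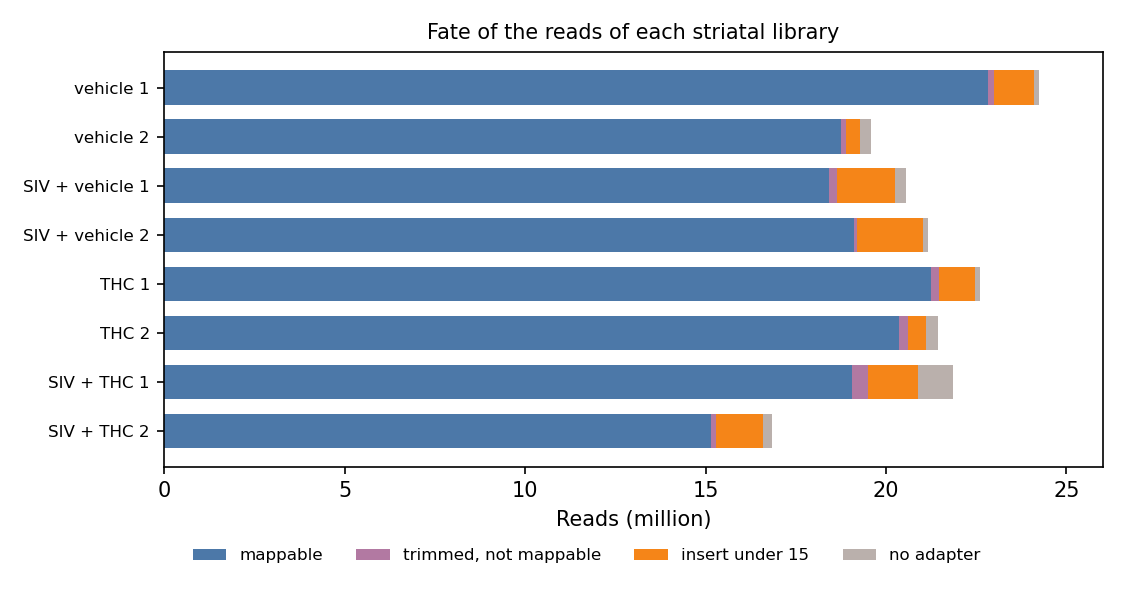
Raw reads of each library in M reads (x axis), divided into mappable reads, trimmed reads that were not mappable, reads with an insert under 15 and reads without adapter, for replicates 1 and 2 of each group (y axis). The short-insert segment spans 1.32 to 1.84 M reads in the 4 infected libraries and 0.392 to 1.11 M in the 4 uninfected ones.

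The first comparison asked whether striatal libraries from SIV-infected animals differed in composition from uninfected ones. Reads with inserts under 15, which are shorter than a mature microRNA, made up a larger share of adapter-containing reads in infected libraries. Their share was 7.82% ± 0.900 (SD, n = 4) with infection and 3.41% ± 1.36 (SD, n = 4) without, a ratio of 2.29. The lowest infected library, SIV with THC replicate 1, was at 6.59%, above the highest uninfected library, vehicle replicate 1, at 4.62%. The difference was 4.41 percentage points, with an exact 97.1% interval from 1.96 to 6.72. The exact permutation p was 0.0286, the smallest that the 70 arrangements allow, and the adjusted p over 12 tests was 0.171. The difference thus passed the unadjusted threshold. The adjusted threshold was out of reach of these 12 tests, whatever the data. With infection labels permuted only within vehicle and within THC, the exact permutation p was 0.0556, the smallest that those 36 arrangements allow. Libraries also formed sets by their share of reads without adapter, so the comparison was repeated within sets. At 0.594% to 0.692% without adapter, the infected library was at 8.75% short inserts and the mean of the 2 uninfected libraries was 4.58%. At 1.40% to 1.57% without adapter, the 2 infected libraries averaged 7.97% and the 2 uninfected ones 2.25%. The remaining library, SIV with THC replicate 1, had no uninfected counterpart. Within sets the difference was 5.10 percentage points. Because all infected libraries lay above all uninfected ones, the direction within any such set was fixed, and these values show only its size.

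The higher short-insert share was present under both agents. Under vehicle it was 8.37% ± 0.545 (SD, n = 2) with SIV and 3.33% ± 1.83 (SD, n = 2) without, a difference of 5.04 percentage points. Under THC it was 7.27% ± 0.961 (SD, n = 2) with SIV and 3.50% ± 1.46 (SD, n = 2) without, a difference of 3.77 percentage points. Each of these comparisons gave an exact permutation p of 0.333, the smallest possible for 2 against 2. The infection difference was 1.27 percentage points smaller under THC, recorded as an interaction of -1.27 (exact permutation p = 0.686, adjusted p = 0.857). In reads, infected libraries held 1.54 M ± 0.240 (SD, n = 4) short inserts and uninfected libraries 0.761 M ± 0.358 (SD, n = 4).

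The mappable share of raw reads was lower in infected libraries. It was 89.2% ± 1.35 (SD, n = 4) with infection and 94.7% ± 0.802 (SD, n = 4) without, a difference of -5.44 percentage points with an exact 97.1% interval from -8.47 to -3.76. The exact permutation p was 0.0286 and the adjusted p was 0.171. This is not a second independent result, because the short-insert reads are removed before mapping. As percentages of raw reads, infected libraries had 4.29 points more short-insert reads, 0.960 points more reads without adapter and 0.193 points more trimmed reads that were not mappable. Among trimmed reads, the mappable share was 98.8% ± 0.739 (SD, n = 4) with infection and 99.1% ± 0.238 (SD, n = 4) without. That difference of -0.27 percentage points was within the spread between libraries (exact permutation p = 0.657, adjusted p = 0.857). Its exact 97.1% interval ran from -1.51 to 0.738, and without SIV with THC replicate 1 the difference was 0.0708 percentage points. The adapter-containing share was 98.0% ± 1.69 (SD, n = 4) with infection and 98.9% ± 0.538 (SD, n = 4) without (difference -0.96 percentage points, exact permutation p = 0.371, adjusted p = 0.800). Without that same library the difference was -0.13 percentage points.

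**Figure D2:**
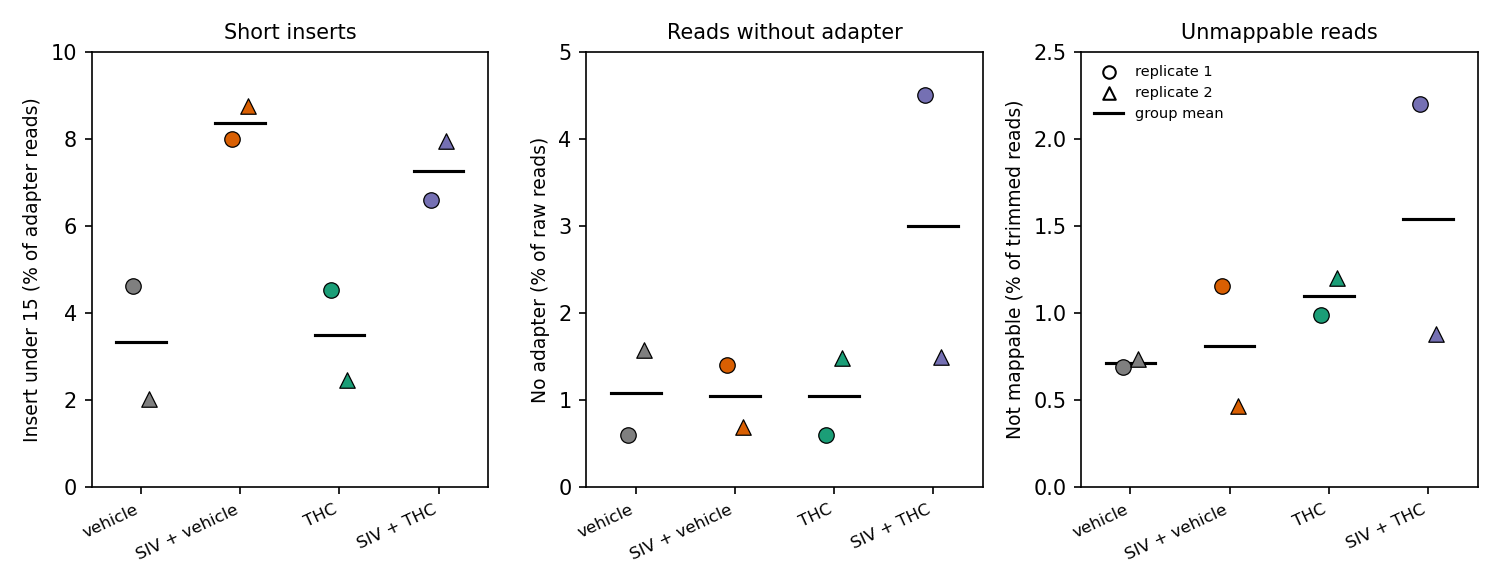
Percent of reads lost at each step (y axes) in the 4 groups (x axes): short inserts among adapter-containing reads, reads without adapter among raw reads, and unmappable reads among trimmed reads. Circles and triangles are replicates 1 and 2 and lines are group means; all 4 infected libraries lie at 6.59% or higher for short inserts and all 4 uninfected ones at 4.62% or lower, while infected and uninfected libraries overlap in the other panels.

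The second comparison asked whether THC changed library composition. No THC difference in a share passed the unadjusted threshold of 0.05. That test ignores infection. With THC labels permuted only within infected and within uninfected libraries, the exact permutation p was 0.611 for the short-insert share and 0.333 for the adapter-containing share. For the mappable share it was 0.167 of trimmed reads and 0.333 of raw reads. Those 36 arrangements allow no p under 0.0556. The short-insert share was 5.38% ± 2.40 (SD, n = 4) with THC and 5.85% ± 3.11 (SD, n = 4) with vehicle, a difference of -0.46 percentage points with an exact 97.1% interval from -6.29 to 5.92 (exact permutation p = 0.800, adjusted p = 0.857). The interval is wide because each level of THC holds infected and uninfected libraries. Within infected libraries the THC difference was -1.10 percentage points, and within uninfected libraries it was 0.171 percentage points (exact permutation p = 0.333 and 1). The mappable share of trimmed reads was 98.7% ± 0.603 (SD, n = 4) with THC and 99.2% ± 0.289 (SD, n = 4) with vehicle. The difference of -0.55 percentage points had an exact 97.1% interval from -1.73 to 0.279 (exact permutation p = 0.114, adjusted p = 0.457). Within uninfected libraries this share was 98.9% ± 0.152 (SD, n = 2) with THC and 99.3% ± 0.0364 (SD, n = 2) with vehicle, with no overlap. That difference of -0.38 percentage points had the smallest exact permutation p that 2 against 2 allow, 0.333. Within infected libraries the difference was -0.73 percentage points (exact permutation p = 0.667). The adapter-containing share was 98.0% ± 1.71 (SD, n = 4) with THC and 98.9% ± 0.494 (SD, n = 4) with vehicle (exact permutation p = 0.400, adjusted p = 0.800). Its THC difference was 0.0417 percentage points within uninfected libraries and -1.95 within infected ones (exact permutation p = 1 and 0.333). The mappable share of raw reads differed by -0.93 percentage points between THC and vehicle (exact permutation p = 0.657, adjusted p = 0.857), with -0.49 within uninfected and -1.37 within infected libraries (exact permutation p = 0.667 for each). Without SIV with THC replicate 1 the THC differences were -0.26 percentage points for the mappable share of trimmed reads, -0.13 for the adapter-containing share and 0.488 for the mappable share of raw reads. The differences within infected libraries rested on single libraries. With each of those 4 left out in turn they ran from -1.78 to -0.42 percentage points for the short-insert share, -3.46 to -0.45 for the adapter-containing share, -1.39 to -0.067 for the mappable share of trimmed reads and -2.69 to -0.055 for that of raw reads. In each range the first value left out SIV with THC replicate 2 and the second replicate 1.

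The third comparison asked whether the effect of infection depended on THC. The interaction was -1.99 percentage points for the adapter-containing share (exact permutation p = 0.286, adjusted p = 0.800). For the mappable share it was -0.35 percentage points of trimmed reads and -0.88 of raw reads (exact permutation p = 0.857 for each, adjusted p = 0.857). The first of these values rested on SIV with THC replicate 1, in which 4.50% of reads lacked the adapter against 0.594% to 1.57% in the other libraries. Without it the interactions were -0.49 percentage points for the adapter-containing share, 0.315 for the mappable share of trimmed reads and 0.437 for that of raw reads. With each library left out in turn, the interaction in the adapter-containing share ran from -3.50 to -0.49 percentage points, the first without SIV with THC replicate 2. Of the 12 tests of shares, 2 passed an unadjusted p of 0.05, both for infection. None passed an adjusted p of 0.05, which no outcome of these tests could have done.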

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

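The infection differences in the short-insert share and in the mappable share of raw reads kept their direction under every alternative run, and both lost the unadjusted threshold under some. With labels permuted within the other factor they were 4.41 and -5.44 percentage points at an exact permutation p of 0.0556, which is the smallest p that 36 arrangements allow. With the replicate number as a replicate block, the same 4.41 and -5.44 percentage points again had an exact permutation p of 0.0556. The labels do not say that a number marks a shared batch, and the deviations of same-numbered libraries from their group means, over 4 scaled measures, had uncentred correlations of -0.71 to 0.810 across the 6 pairs of groups. Only 3 of these were above 0.1, so the numbers were not taken to pair the samples across all groups. The 3 were 0.810 for vehicle with THC, 0.650 for the SIV groups with each other, and 0.216 for vehicle with the group given SIV and THC. Same-numbered libraries thus did deviate together within each infection level, and a batch tied to the numbers there is not excluded. As differences of medians the values were 4.47 and -4.77 percentage points, at an exact permutation p of 0.0571, since several arrangements share the extreme median. Within sets of like adapter-free share, a split added after seeing the data, they were 5.10 and -4.87 percentage points, with an exact permutation p of 0.0556. Except within sets, the complete separation of infected from uninfected libraries fixes these p-values at the smallest possible, so they say nothing about stability. Of trimmed reads in place of raw reads, the infection difference in the mappable share was -0.27 percentage points, and of raw reads in place of trimmed reads it was -5.44, because trimmed reads leave out both the short inserts and the reads without adapter. With each library left out, the short-insert difference was 3.94 to 4.82 percentage points. For the mappable share of raw reads it was -5.76 to -4.77. The exact permutation p was always 0.0286, which separation alone did not fix. The logit scale, the percent of raw reads, and the added log2 tally and log2 ratio to mappable reads also separated infected from uninfected short-insert values, which fixes the call on each scale. Of 35 results, 17 changed sign when some library was left out, none of them past the threshold; the cause was not tested. For log2 library totals the ranges were -0.10 to 0.0428 (THC), -0.32 to 0.0533 (interaction), -0.22 to 0.0900 (infection within vehicle), -0.14 to 0.168 (THC within uninfected) and -0.31 to 0.0677 (THC within infected). For the adapter-containing share they were -0.45 to 0.526 (infection within vehicle) and -0.45 to 0.531 percentage points (THC within uninfected). For the short-insert share they were -1.74 to 0.507 (THC), -2.57 to 0.0253 (interaction) and -1.13 to 1.47 percentage points (THC within uninfected). For the mappable share of trimmed reads they were -0.51 to 0.0708 (infection), -1.01 to 0.315 (interaction), -0.44 to 0.248 (infection within vehicle) and -1.10 to 0.217 percentage points (infection within THC). For the mappable share of raw reads they were -2.08 to 0.488 (THC), -2.20 to 0.437 (interaction) and -1.27 to 0.288 percentage points (THC within uninfected). Apart from these, the THC difference in log2 library totals turned to 0.0538 as a difference of medians, and the adapter-containing share for infection within vehicle turned to -0.018 on the logit scale. Counting intervals at this depth are at most 0.0288 percentage points wide.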

Other observations

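The comparison with each library left out and the infection comparison of the mappable share were planned, and the other tests in this part were chosen after the values had been seen. Adapter sequence was found in 95.5% to 99.4% of raw reads, so almost every insert was shorter than the read. The labels name a library kit known for messenger RNA, while the series is typed as non-coding RNA profiling. Libraries of fragmented messenger RNA with inserts longer than the read would leave most reads without adapter. The lowest share, 95.5%, argues against that kind of library, and a small RNA preparation is a candidate explanation that the labels do not state. The mappable reads available for counting were 17.9 M ± 1.88 (SD, n = 4) in infected and 20.8 M ± 1.70 (SD, n = 4) in uninfected libraries.

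The pattern most open to follow-up is the larger share of inserts under 15 in SIV-infected striatum. Fewer reads in total do not account for it, because the lowest infected tally exceeded the highest uninfected one by 0.205 M reads. At like depths the tally largely restates the share, so it cannot tell more short fragments from fewer longer ones. A single library does not carry the pattern, because the smallest difference with a library left out was 3.94 percentage points. Size selection or a batch might move libraries along the trend of short inserts with adapter-free reads. That trend within infection levels predicts -0.68 percentage points for infected minus uninfected (-0.99 to -0.27 with each library left out), and the observed interval begins at 1.96. At the slope of -0.70 a prediction of 1.96 was out of reach, since uninfected libraries averaged only 1.06% of reads without adapter. Without SIV with THC replicate 1 the slope was -2.06. The infected excess in adapter-free reads was then 0.133 percentage points, against 0.960 with that library. The comparison therefore cannot decide on size selection or a batch. RNA integrity or a preparation step that differed with infection stays open: the mappable share of trimmed reads differed by -0.27 percentage points with overlapping libraries, which decides nothing, and neither RNA integrity nor preparation dates were at hand. A response of the tissue to infection, such as more small RNA fragments, may equally give this pattern and was not tested.

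Within each infection level, libraries with more reads lacking the adapter had fewer short inserts, in exactly opposite order. Among uninfected libraries this order was mainly a split by replicate number. Those numbered 1 had 0.594% (vehicle) and 0.601% (THC) without adapter, with 4.62% and 4.53% short inserts. Those numbered 2 had 1.57% and 1.48%, with 2.03% and 2.47% short inserts. Infected libraries as a level were not ordered by number. Within each SIV group, however, number 1 had more reads without adapter and fewer short inserts than number 2. Without adapter the values were 1.40% and 0.692% (vehicle) and 4.50% and 1.49% (THC). Short inserts were at 7.98% and 8.75% (vehicle) and 6.59% and 7.95% (THC). The number thus went with both shares in all 4 groups, in opposite directions between infection levels. For values centred on the mean of each level, Pearson's r was -0.77 (exact permutation p = 0.0017, adjusted p = 0.0052) and, for ranks within levels, Spearman's rho was -1 (exact permutation p = 0.0035, adjusted p = 0.010), over 8 libraries and 3 relations between shares. These tests treat the libraries of a level as exchangeable, so the p-values may be too small if the replicate numbers mark a batch. Without SIV with THC replicate 1 and vehicle replicate 1, the libraries farthest from the median adapter-free share, r was -0.93 (exact permutation p = 0.0278) and rho was -1 (exact permutation p = 0.0556). Longer inserts in some libraries, as from size selection, may move both shares in opposite directions, but the r of -0.77 is the pattern itself and insert lengths were not at hand, so this stays open.

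The share without adapter also ran with the unmappable share of trimmed reads (r = 0.908, exact permutation p = 0.0295, adjusted p = 0.0443; rho = 0.600, exact permutation p = 0.212, adjusted p = 0.212), and short-insert and unmappable shares gave r = -0.58 (exact permutation p = 0.0729, adjusted p = 0.0729) and rho = -0.60 (exact permutation p = 0.212, adjusted p = 0.212). SIV with THC replicate 1 had both the highest adapter-free share, 4.50%, and the highest unmappable share, 2.20%.

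Among uninfected libraries, the short-insert share averaged 4.58% in replicates numbered 1 and 2.25% in those numbered 2, and among infected libraries 7.29% and 8.35%. The uninfected split is the same contrast as the opposite order with adapter-free reads above. The infected difference by number is part of that order, and neither is a separate result. The infection difference was 2.71 percentage points in number 1 and 6.10 in number 2, and the first minus the second was -3.39 percentage points (exact permutation p = 0.111 over 36 arrangements of the numbers within infection levels).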
